A study of Rattus norvegicus with 32 samples.

How the data were processed

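Total RNA of rat pineal glands and of 6 other tissues was labelled with biotin, from 4 ug per array, and hybridised to 32 one-colour Affymetrix oligonucleotide arrays. Sprague-Dawley rats lived under 14 h of light and 10 h of darkness. Pineal glands were taken at Zeitgeber time 7 (mid-day, 4 arrays) and Zeitgeber time 19 (mid-night, 4 arrays), and each of these arrays held a pool of glands. Retina, cerebellum, cortex, hypothalamus, liver and heart each had 1 day and 1 night array. Glands kept in culture medium for 48 h were left untreated or received norepinephrine (1 uM), dibutyryl cAMP (DBcAMP) or forskolin (10 uM) for 6 h, with 3 arrays per group. The labels give 0.5 or 1 mM for DBcAMP without saying which array had which, so no dose is attached to its values. Nothing in the labels says which cultures, pools or days the replicates came from, so the p-values measure the spread between these samples, which may be partly technical. Groups and replicate numbers were read from the sample titles and source names.

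The values are linear intensity values per probe set, deposited by the authors as 1 table. They were made with MAS5, per the submitters' processing notes, in a version not given in the sources used here. MAS5 summarises the probes of a probe set into 1 value and can scale each array to a common trimmed mean. In the table the mean of each array after trimming 2 percent at each end lay between 100.02 and 100.05, so the scale was read as linear and already set between arrays. Such scaling removes any difference in total RNA between samples, and every change reported is relative to the rest of the same array. Array medians lay between 26.1 and 46.0. Dim probe sets carry mostly background at this scale, and the number of arrays limits the precision.

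The table held 31099 probe sets, of which 57 control probe sets were kept out of all tests. Gene symbols came from the platform annotation. A lookup of their gene identifiers in the RefSeq gene table of the GRCr8 assembly, used for names alone and for no coordinates, changed 0 symbols. Of the 31042 probe sets analysed, 20826 had 1 symbol, 436 had several and 9780 were unnamed here; the first kind covered 14217 genes. Older synonyms in the gene lists were followed only where the stated symbol was not itself a current symbol, a rule tightened after the list values had been seen because some synonyms had led to another gene. All columns of the table were used.

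Intensities were analysed as log2(value + 16) with no further scaling. Fold changes on this scale understate the changes of dim genes. A probe set was tested where its mean in at least 1 group of the fit lay above the 40th percentile of all log2 values of the fit. Linear models were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, with statmod 1.5.0 installed for the robust prior among the alternatives), two-sided, with Benjamini-Hochberg adjustment over the probe sets tested. A probe set was called changed at an adjusted p under 0.05 and a difference of at least 2-fold. Night was compared with day on the 8 in vivo pineal arrays. Each agent, namely norepinephrine (the transmitter released by the sympathetic nerves of the gland), DBcAMP (a cell-permeable analog of cAMP) or forskolin (an activator of adenylyl cyclase), was compared with the untreated cultures, and the agents with each other, in 1 fit of the 12 culture arrays. The difference of the night effect from the norepinephrine or DBcAMP effect, and untreated cultures against day glands, came from 1 fit of all 20 pineal arrays. Tissues were compared on the 20 in vivo arrays, where the day and night array of a tissue served as its 2 arrays, so that no day and night difference of a single tissue was tested. A probe set was called pineal-enriched if it was at least 8-fold above each of the 6 tissues, and shared with the retina if both pineal gland and retina were at least 4-fold above each of the other 5, each at an adjusted p under 0.05. Overlaps of calls were tested with Fisher's exact test, which treats probe sets or genes as independent. Its p therefore does not measure the spread between arrays. Correlations of fold changes are across probe sets, which are not independent replicates, and carry no p-value.

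In all, 30 gene lists for pathways, regulators and cell types were tested with limma's camera at a preset inter-gene correlation of 0.01, on 1 probe set per gene, with Benjamini-Hochberg adjustment over the 28 lists (29 in the fit of 20 arrays) with at least 3 genes tested. The correlation estimated per list was the alternative, and fry gave a self-contained test. Named genes were the list members, the 10 largest rises and 10 largest falls of a comparison among called genes whose groups did not overlap (5 per direction between agents), and the 15 pineal-enriched genes with the largest ratio to the next tissue. For differences between effects the largest were taken by call alone. The probe set with the highest mean spoke for a gene with several. The groups, tests, thresholds, lists, the rule for named genes and most alternatives were fixed before the data were examined.

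The same steps were tested on simulated data with 200 probe sets changed by known amounts. For night versus day 47.8 percent of the 2-fold, 97.0 percent of the 4-fold and all 66 of the 8-fold changes were called, with 2 false calls. The corresponding shares at 2-fold were 47.8 percent for norepinephrine, 58.2 percent for DBcAMP, 44.8 percent for forskolin, 50.7 percent for untreated culture against day and 26.9 percent for the night effect minus the norepinephrine effect. At 4-fold they lay at 100 percent for the 3 agents, 97.0 percent for culture against day and 95.5 percent for the difference of effects. A list of 20 genes shifted in the simulation was found and the remaining 28 were not called. The simulated genes varied independently, so this does not show how the list test behaves where genes vary together.

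Alternatives were offsets of 1 and 64, quantile normalization, centring of each array on its median, no filter or one at the 60th percentile, an intensity trend with a robust prior, all 20 pineal arrays in 1 fit, the replicate number as a block, and leaving out each array in turn. Alternatives added after seeing the data are named as such where their values are given. For comparisons against shared control arrays, 50 simulations gave the overlap, correlation and covariance that shared controls bring about among unchanged groups.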

Results

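RNA levels were measured on 32 arrays from rat. Of these, 20 came from the pineal gland, the gland that makes melatonin at night: 4 pools of glands taken at mid-day, 4 pools taken at mid-night, and 3 arrays each of glands cultured untreated, with norepinephrine, with dibutyryl cAMP (DBcAMP) or with forskolin. The other 12 arrays held 1 day and 1 night sample each of retina, cerebellum, cortex, hypothalamus, liver and heart. Array medians lay between 26.1 and 46.0 on a scale whose trimmed mean was about 100 on every array. The study concerned the daily rhythm of pineal gene expression and how far adrenergic stimulation and cAMP reproduce it in culture.

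The night and day arrays asked which pineal RNAs follow the daily rhythm. At mid-night Aanat, the enzyme that acetylates serotonin and controls the rate of melatonin synthesis, was 61.5-fold higher (log2 difference 5.94 ± 0.13 SE, adjusted p = 2.8e-08), with an intensity of 2619 ± 219 at night and 27.0 ± 5.83 by day (SD, n = 4 each). The peptide transporter Slc15a1 rose 49.5-fold, from 27.2 ± 3.48 to 2166 ± 528, and the high-affinity IgE receptor subunit Fcer1a rose 13.5-fold, from 192 ± 24.1 to 2794 ± 84.7. The largest fall was that of Hs3st2, a heparan sulfate sulfotransferase, from 1056 ± 232 by day to 43.6 ± 10.2 at night (17.9-fold, adjusted p = 3.0e-06). In all, 375 probe sets were higher at night and 178 lower, among 19356 tested, which named 222 and 116 genes; 88 of the rises and 14 of the falls were at least 4-fold.

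Further large rises were those of the kinase Sik1 (17.6-fold), Ribc2 (15.8-fold), the kinase Dclk3 (13.4-fold), the insulin receptor substrate Irs2 (11.7-fold), Irak2 (11.5-fold), the surface protein Cd24 (11.1-fold) and the copper transporter Atp7b (9.81-fold). The chemokine Ccl9 fell 10.2-fold and the phosphatase Ptpn21 fell from 295 ± 24.7 to 32.4 ± 9.01. The kinase Sgk1 (4.74-fold), the sialyltransferase St8sia3 (4.09-fold), the protease inhibitor Tfpi2 (4.05-fold), Tmem215 (3.96-fold) and Pdzph1 (3.90-fold, not called with offset 64) were also lower at night. Of the 7 genes of melatonin synthesis tested, 1 rose (Aanat) and 6 did not pass. Asmt, which makes melatonin from N-acetylserotonin, measured 1644 ± 284 at night and 1357 ± 345 by day (log2 difference 0.30, adjusted p = 0.462), and the decarboxylase Ddc differed by 0.54 (adjusted p = 0.0417), under the 2-fold threshold and with another probe set of opposite sign.

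Of the 21 cAMP-responsive and immediate early regulators tested, 8 rose and 0 fell (camera adjusted p = 2.6e-09; adjusted p = 0.0110 with an estimated correlation). They included Sik1, the cAMP-responsive regulator Crem (8.81-fold, 288 ± 14.9 to 2720.0 ± 645), the phosphatase Dusp1 (8.96-fold) and the orphan receptor Nr4a1 (5.37-fold). Of 20 adrenergic and cAMP signalling genes 5 rose (adjusted p = 8.0e-04; adjusted p = 0.0788 with an estimated correlation), among them the phosphodiesterases Pde10a (8.34-fold), Pde4b (3.80-fold) and Pde4d (2.68-fold) and the receptor Adra1b (2.25-fold). Of 19 endoplasmic reticulum stress genes 3 rose, including the chaperone Hspa5 (2.65-fold) and the transcription factor Xbp1 (2.26-fold), with an adjusted p of 4.1e-07 for the list (adjusted p = 0.145 with an estimated correlation). Of 11 heat shock genes 3 rose, such as Hspa1a (3.61-fold) and Hsph1 (2.37-fold), and 1 fell (adjusted p = 3.0e-04; adjusted p = 0.258 with an estimated correlation). The fall was that of Hspb1 (2.10-fold, adjusted p = 0.0368), a call that ended without day array 1, 3 or 4 or night array 3 or 4, with offset 1, median centring or no filter, and with arrays 3 and 4 averaged, a choice made after seeing the data (adjusted p from 0.0543 to 0.147). The phototransduction list shifted down (adjusted p = 0.0203; adjusted p = 0.211 with an estimated correlation), with 2 of 27 genes called lower, the cyclic nucleotide-gated channel Cnga1 (2.51-fold) and Pdc, a regulator of transducin signalling (2.78-fold, adjusted p = 0.0372). The call of Pdc ended, leaving 1 of 27, without day array 1, 3 or 4 or night array 3 or 4, with offset 1 or no filter, and with arrays 3 and 4 averaged, likewise chosen afterwards (adjusted p from 0.0555 to 0.196). The MAPK feedback list had 1 rise (Dusp1) among 6 genes (adjusted p = 0.0492; adjusted p = 0.239 with an estimated correlation). Outside these lists with a shift, the thyroid hormone receptor Thrb rose 2.36-fold, the transporter Slc17a6 rose 3.84-fold and Isl2, a homeobox factor, fell 2.71-fold.

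Of 20 circadian clock genes 4 rose at night and 1 fell, and the list lay higher than other genes by its test (adjusted p = 0.00414; adjusted p = 0.258 with an estimated correlation). Per2 rose from 25.7 ± 6.49 to 148 ± 39.1 (3.88-fold), the nuclear receptor Rorb rose 3.80-fold and Cry2 rose 2.52-fold. Nr1d1, a repressor of the clock loop, fell from 202 ± 48.1 to 63.3 ± 38.7, a call that ended without day array 1 (adjusted p = 0.0561) or night array 3 (adjusted p = 0.0572), or with arrays 3 and 4 averaged after seeing the data (0.0883). Per1 rose 2.62-fold (log2 difference 1.39 ± 0.31 SE), a call that ended without day array 1 (adjusted p = 0.0639), day array 4 (0.0601) or night array 1 (0.0664), or with offset 64, where the difference was 0.74. Dbp, a clock output factor, differed by -0.34 (adjusted p = 0.685) and Bmal1 by -0.11, neither past the test. On the night arrays Dbp averaged 394 on replicates 1 and 2 and 108 on replicates 3 and 4.

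**Figure D1:**
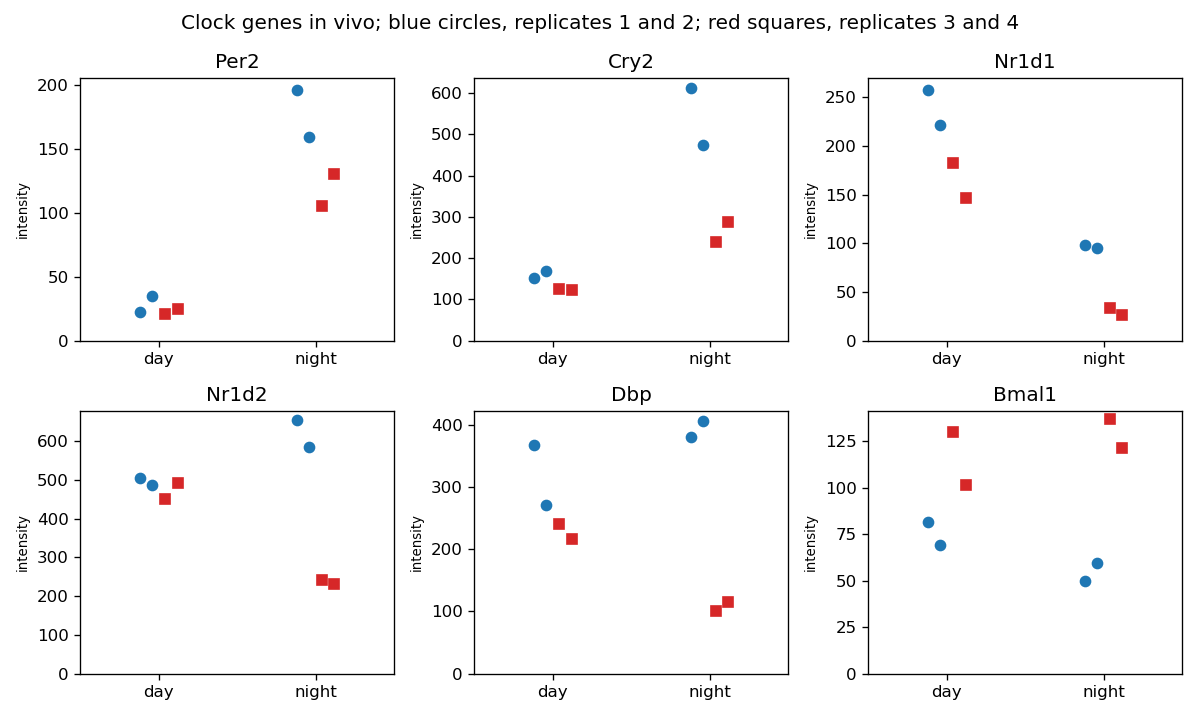
Intensity of 6 clock genes on the 4 day and 4 night pineal arrays, on linear axes that start at 0, with replicates 1 and 2 as blue circles and replicates 3 and 4 as red squares. Per2 was higher on every night array than on every day array, and at night Dbp, Nr1d2 and Nr1d1 were higher on replicates 1 and 2 than on replicates 3 and 4.

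Adjusted over the list alone, the counts of the lists named so far for night and day were the same. Arrays 3 and 4 of each time were closest to each other, with an SD of log2 differences of 0.136 by day and 0.118 at night over 1772 bright probe sets against 0.247 to 0.576 for the other in vivo pairs. With arrays 3 and 4 averaged as 1 replicate, 307 probe sets were higher and 127 lower, and with replicates 1 and 2 against 3 and 4 as a block 399 were higher and 192 lower, both chosen after seeing the data. Without day array 2, whose actin 3 prime to 5 prime ratio stood apart (log2 3.14), 270 were lower.

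Norepinephrine, the transmitter of the sympathetic nerves that reach the gland, was given to cultured glands for 6 h and raised Aanat and other genes. Aanat rose 35.2-fold over untreated cultures (log2 difference 5.14 ± 0.13 SE, adjusted p = 8.0e-11), from 20.5 ± 6.65 to 1256 ± 72.7 (SD, n = 3 each). Fcer1a rose 17.3-fold, Slc15a1 13.9-fold, Sik1 11.3-fold and the neuronal pentraxin Nptx1 8.38-fold, the last from 486 ± 122 to 4112 ± 109. Hs3st2 fell 5.48-fold, from 494 ± 96.4 to 76.5 ± 13.8. Among 20191 probe sets tested 270 were higher and 124 lower, naming 183 and 68 genes. With each array centred on its median, 327 were higher and 84 lower.

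Other large rises with norepinephrine were Dclk3 (8.39-fold), the sulfotransferase Chst2 (6.40-fold) and the vesicular glutamate transporter Slc17a6 (4.88-fold). The methionine sulfoxide reductase Msrb2 fell 4.28-fold, Pdc 3.73-fold, Tmem215 3.71-fold, Ptpn21 3.55-fold, the somatostatin receptor Sstr3 3.36-fold and the guidance receptor Plxna4 3.32-fold. Of 24 cAMP-responsive and immediate early regulators 6 rose and 0 fell (adjusted p = 7.9e-08; adjusted p = 0.0558 with an estimated correlation), with Crem (7.43-fold, 371 ± 27.1 to 2864 ± 267), Dusp1 (7.94-fold), Nr4a1 (4.92-fold) and Fosl2 (3.97-fold) among them. Of 25 adrenergic and cAMP signalling genes 5 rose (adjusted p = 0.0118; adjusted p = 0.125 with an estimated correlation), such as Pde10a (6.76-fold), the G-protein regulator Rgs2 (4.19-fold) and Adra1b (3.60-fold). Glycolysis, cholesterol synthesis and endoplasmic reticulum stress genes each shifted up as lists with 0 members called (adjusted p = 0.0118 each; adjusted p = 0.398 each with an estimated correlation). In the thyroid hormone and retinoic acid list 2 of 16 genes rose, the deiodinase Dio2 from 3.77 ± 2.78 to 41.9 ± 8.79 and Thrb 2.29-fold, with a list adjusted p of 0.218. In the clock list 2 rose, Cry2 (2.16-fold) and the repressor Nfil3 (2.20-fold), and 1 fell among 20 (list adjusted p = 0.269), Per3 by 2.34-fold, a call that ended without control array 2, where the difference was -0.98. With a single control array, a choice made after seeing the data, the calls of Plxna4, Thrb, Cry2, Nfil3 and Per3 each ended for at least 1 of the 3 controls, that of Per3 against control array 1 (difference -0.69). With offset 64 none of these 5 was called, nor was Fosl2, nor Dio2 (difference 0.64), whose control level lay below the offset of 16 used here.

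Liver transcripts differed between culture arrays: albumin (Alb) measured 15.7, 611 and 264 on the control arrays and 6.73 to 15.3 with norepinephrine, and of 7 liver markers 1 fell (2 when adjusted over the list alone; list adjusted p = 0.135). The fall was that of Alb itself (adjusted p = 0.0285), and the call ended without control array 2 or 3, without any 1 of the 3 norepinephrine arrays, with no filter and with a trend and robust prior (adjusted p from 0.0574 to 0.112), and, in a fit chosen after seeing the data, against control array 1 alone (0.792). Without liver-marked probe sets, a choice made after seeing the data, 269 probe sets were higher and 117 lower with norepinephrine. Adjusted over the list alone, the counts of the other lists given for norepinephrine were the same. For melatonin synthesis the median of the list was -0.04 and its mean 0.73.

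DBcAMP, which enters cells and activates cAMP targets, raised Aanat less than norepinephrine did. Aanat rose 10.2-fold (log2 difference 3.34 ± 0.13 SE, adjusted p = 2.2e-08), to 351 ± 21.3 (SD, n = 3). Nptx1 rose 6.48-fold, Fcer1a 6.07-fold, Slc15a1 5.57-fold and Crem 4.33-fold, and Hs3st2 fell 3.82-fold. In all 128 probe sets were higher and 56 lower, naming 76 and 37 genes, and 8 rises but 0 falls were at least 4-fold.

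Chst2 (3.66-fold) and the photoreceptor transcription factor Crx (2.55-fold) were also higher with DBcAMP, and Ptpn21 (3.24-fold), Msrb2 (3.06-fold), the splicing factor Sfpq (3.01-fold) and the organic anion transporter Slco3a1 (2.78-fold) were lower. Of 24 cAMP-responsive and immediate early regulators 4 rose (adjusted p = 2.1e-04; adjusted p = 0.106 with an estimated correlation), among them Dusp1 (3.80-fold). Of 25 adrenergic and cAMP signalling genes 4 rose (adjusted p = 0.00109; adjusted p = 0.106 with an estimated correlation), with Pde10a (3.68-fold), Adra1b (3.08-fold) and Pde8a (2.48-fold). The call of Crx ended with all 20 pineal arrays in 1 fit (adjusted p = 0.121) and, in fits chosen after seeing the data, against control array 1 alone (0.135) or control array 2 alone (0.222). With offset 64 Pde8a was not called and 2 of the 4 immediate early regulators were. Of 18 glycolysis and glucose transport genes 1 rose, the glucose transporter Slc2a1 from 585 ± 117 to 1355 ± 136 (list adjusted p = 8.4e-05; adjusted p = 0.117 with an estimated correlation). The clock list shifted up with 0 of 20 genes called (adjusted p = 0.0192; adjusted p = 0.106 with an estimated correlation), and so did endothelial markers (adjusted p = 0.0237; adjusted p = 0.437 with an estimated correlation). Melatonin synthesis (1 of 7 called), endoplasmic reticulum stress and microglia lists had an adjusted p of 0.0455 each (adjusted p = 0.437, 0.437 and 0.582 with an estimated correlation). Adjusted over the list alone, these counts were the same.

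Forskolin, which activates adenylyl cyclase, raised Aanat and lowered almost as many probe sets as it raised. Aanat rose 23.6-fold (log2 difference 4.56 ± 0.13 SE, adjusted p = 3.8e-10), to 838 ± 55.3 (SD, n = 3), Fcer1a rose 13.7-fold and the transcription factor Bhlha15 9.92-fold, from 7.64 ± 3.54 to 218 ± 29.1. Hs3st2 fell 7.08-fold, the protease Adamts1 5.12-fold and the retinal dehydrogenase Aldh1a3 4.74-fold. In all 233 probe sets were higher and 224 lower, naming 139 and 162 genes; with each array centred on its median 309 were higher and 149 lower. Forskolin array 2 stood apart in RNA quality, with a log2 actin 3 prime to 5 prime ratio of 3.10 against 2.32 and 1.56 on the other forskolin arrays and a GAPDH ratio of 0.884 against 0.187 and 0.0676, and the mean actin ratio was 2.33 with forskolin and 1.67 in controls. Without forskolin array 2, 223 probe sets were higher and 193 lower, and without forskolin array 3, 363 were lower.

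Slc15a1 (7.14-fold), Crem (6.84-fold), Dusp1 (6.76-fold) and C2cd4a (5.70-fold) were higher with forskolin, and the matrix protein tenascin C (Tnc, 3.79-fold), Fam107a (3.64-fold), the apelin receptor Aplnr (3.47-fold) and Sgk1 (3.33-fold) were lower. Of 25 adrenergic and cAMP signalling genes 6 rose (adjusted p = 0.00515; adjusted p = 0.167 with an estimated correlation), with Pde10a (6.60-fold), Adra1b (5.75-fold) and Pde4d (4.41-fold). Of 24 cAMP-responsive and immediate early regulators 7 rose and 2 fell (adjusted p = 0.00597; adjusted p = 0.181 with an estimated correlation), Nr4a3 rising 4.82-fold, Egr2 falling 3.46-fold and Atf3 falling 2.09-fold. The call of Atf3 ended without control array 1 (difference -0.86) or forskolin array 1 (-0.96), with quantile normalization, median centring or offset 64, and, as a choice made after seeing the data here and below, against control array 2 or 3 alone. Inflammation genes went both ways: 3 of 22 rose, among them the cytokine Il6 (4.20-fold, 22.2 ± 11.6 to 148 ± 67.4) and the chemokine Cxcl2 (3.43-fold), and 8 fell, among them the adhesion molecules Vcam1 (2.67-fold) and Icam1 (2.61-fold) (list adjusted p = 0.284). Of the 8 falls 1 was left with offset 64, Icam1 not being called (difference -0.74), and 5 against control array 2 alone. Among the rises Il6 was not called against control array 3 alone (adjusted p = 0.0564). Nos2 (2.13-fold, adjusted p = 0.0371) was not called with offset 1 or 64, no filter or all 20 pineal arrays in 1 fit, without control array 1 or 3 or any 1 of the 3 forskolin arrays, or against control array 2 alone. Fibroblast and mural cell markers shifted down, 3 of 13 called lower (adjusted p = 6.3e-05; adjusted p = 0.167 with an estimated correlation), as did proliferation genes, 1 of 19 called (adjusted p = 0.00645; adjusted p = 0.637 with an estimated correlation). The 3 marker genes, Col3a1, Acta2 and Col1a2, lay just past 2-fold (2.01 to 2.08-fold), as did the proliferation gene Mcm7 (2.02-fold): with median centring or offset 64, 0 of these were called, without forskolin array 1, or against control array 3 alone, 1 of the 3 markers was, and Mcm7 was not called without forskolin array 2 or control array 1, with quantile normalization or against control array 3 alone. Of 8 astrocyte and glia markers 1 fell, the connexin Gja1 from 4052 ± 636 to 1498 ± 79.9 (list adjusted p = 0.0130; adjusted p = 0.167 with an estimated correlation). Adjusted over the list alone, these counts were the same.

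**Figure D2:**
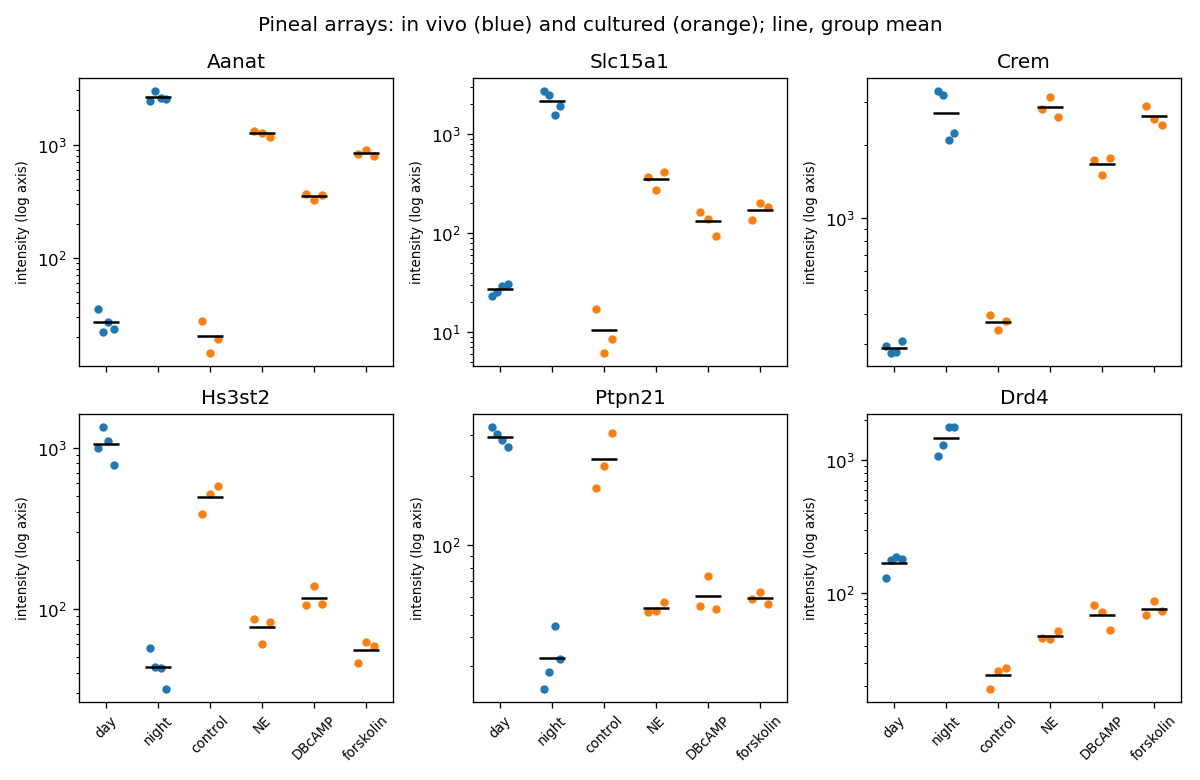
Intensity of Aanat, Slc15a1, Crem, Hs3st2, Ptpn21 and Drd4 on each of the 20 pineal arrays, on a log axis; in vivo arrays are blue, cultured ones orange, and the black line is the group mean. Aanat lay at 27.0 by day and 2619 at night on average, and in culture at 20.5 untreated and 1256 with norepinephrine, while Hs3st2 lay lower at night and with each agent.

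The agents were compared with each other in the same fit. Norepinephrine gave a higher Aanat level than DBcAMP (3.46-fold; 1256 against 351) and forskolin a higher one than DBcAMP (2.32-fold). Against DBcAMP norepinephrine had 110 probe sets higher and 96 lower: Ribc2 (5.58-fold), the receptor Gpr6 (4.00-fold), Id1 (3.41-fold) and Rgs2 (2.88-fold) were higher, and the clock gene Per3 was lower (4.48-fold; 55.5 against 305). Of 24 cAMP-responsive and immediate early regulators 4 were higher with norepinephrine (adjusted p = 0.00145; adjusted p = 0.355 with an estimated correlation), and the phototransduction list lay lower with 0 of 22 called (adjusted p = 0.00145; adjusted p = 0.355 with an estimated correlation). Against forskolin norepinephrine had 204 higher and 151 lower: Tnc (5.15-fold), Adamts1 (4.76-fold), Aldh1a3 (4.18-fold) and Chst2 (3.45-fold) were higher, and C2cd4a (4.90-fold), Tnfaip6 (4.06-fold), the neurofilament Nefh (3.89-fold) and Il6 (2.82-fold) were lower. Fibroblast and mural cell markers were higher with norepinephrine than with forskolin, 3 of 13 called (adjusted p = 5.1e-05; adjusted p = 0.268 with an estimated correlation). Endothelial (0 of 9 called, adjusted p = 0.0181; adjusted p = 0.330 with an estimated correlation) and astrocyte and glia lists (1 of 8, adjusted p = 0.0262; adjusted p = 0.268 with an estimated correlation) shifted up too. Against DBcAMP forskolin had 174 higher, led by C2cd4a (8.03-fold) and Nefh (7.83-fold), and 337 lower, led by Adamts1 (5.28-fold) and Tnc (4.76-fold), with 8 of 13 fibroblast and mural cell markers lower (adjusted p = 1.6e-05; adjusted p = 0.171 with an estimated correlation). Markers of other cell types were lower too. Endothelial (2 of 9 called, adjusted p = 4.9e-04), microglia and macrophage (2 of 14, adjusted p = 5.5e-04), astrocyte and glia (1 of 8, adjusted p = 0.0350) and myelin cell lists (0 of 4, adjusted p = 0.0187) shifted down. With an estimated correlation their adjusted p was 0.171, 0.634, 0.171 and 0.171. In each of the choroid plexus, neuron, retina and blood lists 1 gene was called lower. None of these 4 genes was called with offset 64, nor were the 2 endothelial genes. With that offset 5 of the 8 fibroblast and mural cell markers were called, and neither Gpr6 nor Il6 was. The choroid plexus, neuron and retina genes were not called with all 20 pineal arrays in 1 fit. The neuron and retina genes were also lost without forskolin array 2, and the neuron gene without DBcAMP array 1 or 2. The blood gene was lost with offset 1, no filter, quantile normalization or the replicate block. That gene was also lost without DBcAMP array 2 or 3, or without forskolin array 1 or 3. Adjusted over the list alone, these counts were the same. Between agents 6 lists were called in each comparison and 0 held with an estimated correlation. Without forskolin array 3, norepinephrine had 316 probe sets above forskolin, and without forskolin array 2, which stood apart in RNA quality, 186 above and 161 below; forskolin then had 179 above and 266 below DBcAMP. Each of the 9 treated arrays correlated best with the same control array as the others of its agent: control 1 for norepinephrine, control 2 for DBcAMP and control 3 for forskolin. Against any single control array, a choice made after seeing the data, norepinephrine had 277 to 324 probe sets higher and 93 to 214 lower, DBcAMP 113 to 232 and 50 to 105, and forskolin 209 to 356 and 191 to 357; of the gene calls followed through these settings 100 to 106 were kept and 17 to 23 lost. The cre spike-in, a transcript added to the sample, went largely the same way. It measured 6029 on control array 1 and 5423 to 6848 with norepinephrine. On control array 2 it measured 8034, and 6811 to 8954 with DBcAMP. On control array 3 it measured 3953, and 4136 to 4877 with forskolin. Handling thus differed along with the agent, at least for forskolin. The labels name no culture batch, so a difference between agents and one of culture batch or handling cannot be told apart.

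Because all agents were set against the same 3 untreated arrays, overlaps between agents were read beside values for independent lists and simulated unchanged groups. Norepinephrine and forskolin shared 123 rises and 30 falls, where independent lists would share 3.12 and 1.38 and simulated unchanged groups shared 0; the covariance of their log2 changes was 0.0734 against 0.0136 simulated. Norepinephrine and DBcAMP shared 80 rises and 24 falls (1.71 and 0.344 for independent lists, 0 simulated), with a covariance of 0.0638 against 0.0136. DBcAMP and forskolin shared 64 rises and 13 falls (1.48 and 0.621, 0 simulated), with a covariance of 0.0417 against 0.0136. Correlations across probe sets, which are not independent replicates, were 0.52, 0.55 and 0.34 in that order, and 0.50 in the simulations. Unchanged groups are hardly ever called, so their overlap of 0 does not measure what shared controls add to an overlap of changed genes. The values for independent lists leave the shared controls out. Part of the excess may come from the shared controls, since 3 arrays cannot be split into sets of at least 2 each.

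The calls in vivo were set against those in culture, which share no array. Of 363 probe sets higher at night and tested in both fits, norepinephrine raised 167 (46.0 percent; 5.20 expected, Fisher's exact p = 1.6e-231), forskolin 124 (34.2 percent; 4.24 expected, p = 1.4e-160) and DBcAMP 65 (17.9 percent; 2.42 expected, p = 8.5e-79). Of 161 lower at night, norepinephrine lowered 32 (19.9 percent; 0.996 expected, Fisher's exact p = 5.8e-40), forskolin 26 (16.1 percent; 1.77 expected, p = 4.7e-23) and DBcAMP 12 (7.45 percent; 0.446 expected, p = 1.5e-14; 18 without control array 1). At least 1 agent raised 195 of the 363 (53.7 percent) and all agents 47, such as Aanat, Fcer1a, Slc15a1 and Crem, and at least 1 lowered 40 of the 161 (24.8 percent) and all agents 8, such as Hs3st2 and Ptpn21. Called or not, 96.1 percent of the 363 and 93.8 percent of the 161 moved the same way with norepinephrine as at night. The shares were 89.3 and 89.4 percent with forskolin and 81.5 and 85.7 percent with DBcAMP. A probe set that was not called with an agent was therefore not shown to be unresponsive to it. Across the 524 probe sets chosen for their change at night, the correlation of log2 changes was 0.85 with norepinephrine, 0.76 with forskolin and 0.72 with DBcAMP. Probe sets are not independent replicates, so these correlations carry no p. For the same reason the p-values of Fisher's exact test describe the overlap of lists and do not measure the spread between arrays.

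**Figure D3:**
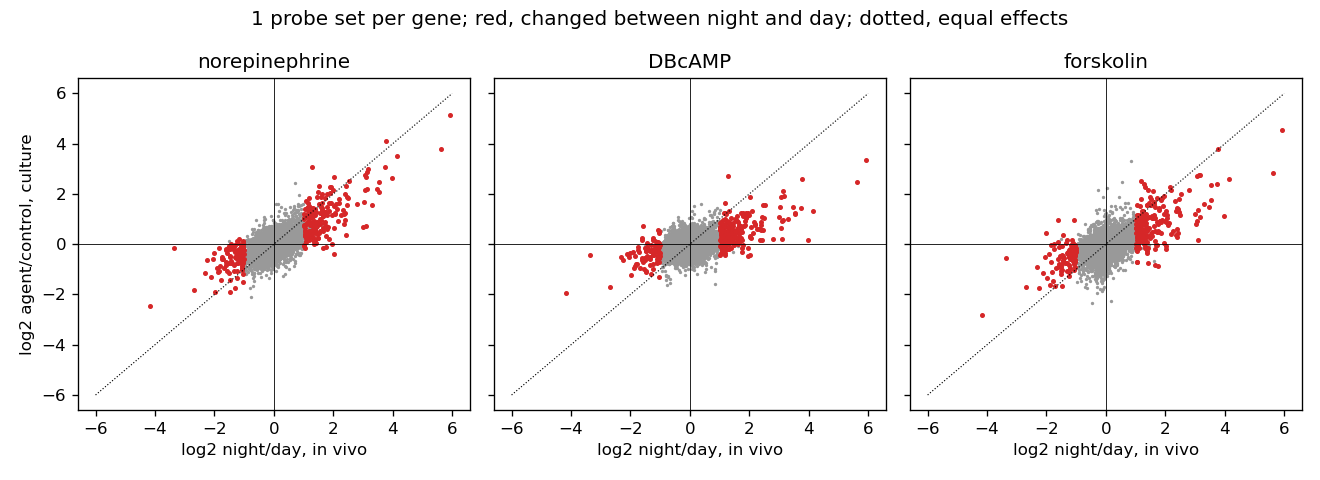
Log2 difference of night against day in vivo (horizontal) and of an agent against untreated culture (vertical), 1 probe set per gene, for norepinephrine, DBcAMP and forskolin; red points changed between night and day and the dotted line marks equal effects. Over all probe sets tested in both fits the correlation was 0.60 for norepinephrine, 0.34 for DBcAMP and 0.43 for forskolin.

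The difference between the night effect and an agent's effect was tested itself. Untreated cultures and day glands started from unlike levels, so such a difference need not be one of response alone. The night effect exceeded that of norepinephrine for the dopamine receptor Drd4 by 2.33 ± 0.24 (log2 ± SE, adjusted p = 4.3e-05), for the axon guidance factor Draxin by 2.39 (a call that ended with offset 1) and for Per2 by 1.95. Nptx1 rose more with norepinephrine (difference -1.79), and the fall of Ccl9 was larger in vivo (-3.21). In all 118 probe sets had a higher and 84 a lower night effect. Endoplasmic reticulum stress genes (adjusted p = 0.00974; adjusted p = 0.393 with an estimated correlation) and heat shock genes (adjusted p = 0.0135; adjusted p = 0.393 with an estimated correlation) had the higher shift at night, with 0 of 19 and 1 of 11 genes called (1 and 1 when adjusted over the list alone). The heat shock gene was Hspa1a (difference 1.63, adjusted p = 0.0302), a call that ended with offset 1 and, in fits chosen after seeing the data, without day array 3 or 4, night array 1, control array 2 or 3 or norepinephrine array 1 or 3 (adjusted p from 0.0501 to 0.104). Against DBcAMP, 316 probe sets had a higher and 197 a lower night effect (350 lower without day array 2, a choice made after seeing the data), including Slc15a1 (3.15), Sik1 (2.80, with another probe set of opposite sign) and Aanat (2.60 ± 0.18 SE, adjusted p = 1.2e-07). Of 24 cAMP-responsive and immediate early regulators 6 had the larger night effect (adjusted p = 3.5e-05; adjusted p = 0.00278 with an estimated correlation), the same count when adjusted over the list alone.

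Untreated cultures differed widely from mid-day glands, and culture cannot be told apart from any difference of batch between these arrays. The matrix protein osteopontin (Spp1) was 49.9-fold higher (1815 ± 354, n = 3, against 21.1 ± 8.94, n = 4; SD; adjusted p = 6.2e-11), and the acute phase inhibitor Serpina3n 34.1-fold, the chemokine Ccl2 13.8-fold and heme oxygenase Hmox1 12.3-fold higher. Beta globin (Hbb) was 67.2-fold lower, the cone opsin Opn1sw 21.5-fold lower, and Asmt fell from 1357 ± 345 to 135 ± 22.7 (8.90-fold). In all 922 probe sets were higher and 679 lower among 21261. The median of all probe sets shifted by 0.12 on the log2 scale, against 0.02 after quantile normalization and -0.07 with each array centred on its median, and the last gave 589 higher and 1087 lower.

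Of 27 phototransduction genes 17 were lower in culture and 1 higher (adjusted p = 4.0e-16; adjusted p = 9.6e-05 with an estimated correlation), among the lower ones the cone arrestin Arr3 (9.47-fold), the kinase Grk1 (8.50-fold) and the transducin subunits Gnat2 (8.20-fold) and Gngt2 (8.41-fold). Proliferation genes were higher, 11 of 19 called, such as Cdk1 (5.08-fold) and Mki67 (4.01-fold) (adjusted p = 1.8e-07; adjusted p = 0.0381 with an estimated correlation). Of 24 cAMP-responsive and immediate early regulators 10 were higher (adjusted p = 9.0e-06; adjusted p = 0.00126 with an estimated correlation). Inflammation (11 of 23 higher, adjusted p = 5.1e-05; adjusted p = 0.118 with an estimated correlation), endoplasmic reticulum stress (5 of 19, adjusted p = 5.9e-05; adjusted p = 0.0607 with an estimated correlation) and microglia genes (6 of 14, adjusted p = 0.00741; adjusted p = 0.316 with an estimated correlation) also shifted up. Mitochondrial respiration genes shifted down with 0 of 29 called (adjusted p = 6.7e-05; adjusted p = 0.316 with an estimated correlation), and blood, melatonin synthesis and choroid plexus lists each had 2 lower genes (adjusted p = 0.0132, 0.0267 and 0.0333; adjusted p = 0.118, 0.149 and 0.186 with an estimated correlation). Of the melatonin synthesis genes Ddc (2.03-fold) was not called without day array 3 or 4 or control array 3, or with quantile normalization or offset 64. With offset 64 the counts left were 2 of 11 proliferation, 4 of 11 inflammation and 2 of 6 microglia genes. Adjusted over the list alone, these counts were the same. Of 12 lists called, 3 held with an estimated correlation.

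Across tissues, 23 probe sets of 19 named genes were at least 8-fold above each of the 6 other tissues in the pineal gland, among 25353 tested. Spink4 led with 31.1-fold over the next tissue, followed by Asmt (24.8-fold), Defb24 (24.2-fold), Esm1 (23.7-fold) and the nicotinic receptor subunit Chrna3 (22.8-fold). Col8a1 (19.4-fold), Slc15a1 (13.7-fold), the lipoxygenase Alox15 (12.8-fold), Slc23a4 (12.3-fold), Nphs1 (12.2-fold) and the nicotinic subunit Chrnb4 (12.1-fold) came next, and Lrrc38, Gngt2, Isl2 and Fyb1 lay between 10.1 and 11.6-fold. These folds average day and night on the log2 scale; Slc15a1 measured 27.2 by day and 2166 at night, against 6.36 in retina. Of the 23, 6 also changed between night and day: 4 were higher at night, among them Slc15a1, Aanat and Ncaph, and both probe sets of Isl2 were lower. Aanat measured 27.0 by day, against 22.9 in hypothalamus, its next tissue. A rise at night itself raises the average used for enrichment, so Fisher's exact test of this overlap (p = 3.6e-05) was not read as a result. The pineal gland and retina shared 74 probe sets of 56 genes at least 4-fold above the other 5 tissues. These included 17 of 32 phototransduction genes (odds ratio 363, Fisher's exact p = 2.9e-33). The retina requirement itself favours such genes: their median log2 value was 10.2 in retina, 8.64 in pineal gland and 4.56 to 4.86 in the other 5. The odds ratio and p, taken over all genes tested, therefore do not measure how far the pineal gland shares the pathway. Among the shared genes were arrestin Sag (1536 ± 258 in the day pineal, 8194 as mean of the 2 retina arrays), the transducin subunit Gnat2 (1429 ± 106 and 182) and the homeobox factor Otx2 (2541 ± 626 and 1929). The cre spike-in, a transcript added to the sample, measured 3255 to 8954 on the pineal, retina and cerebellum arrays and 0.392 to 2.52 on those of cortex, hypothalamus, liver and heart, so for these 4 tissues a difference of handling and of tissue cannot be told apart. Without the cortex night and heart night arrays, on which liver transcripts were seen, 21 probe sets were pineal-enriched and 72 shared, a choice made after seeing the data.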

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

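The quality values, differences between effects and splits given here were planned, while the splits with arrays 3 and 4 averaged were tests chosen only after the result was seen. On day array 2 the actin 3 prime to 5 prime ratio was 3.14 on the log2 scale, the same ratio of GAPDH was 0.851 and the 5S ribosomal RNA intensity was 955, each far from the other 3 day arrays. Among the 4 day pineal arrays, array 1 had the lowest cre spike-in intensity, 3255, and array 4 the highest Atp7b intensity, 101. These were 5 such values among 58 sets of 4 arrays, where chance flags about 1 in 20 groups (2.9 expected).

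The night effect differed from the norepinephrine effect, by the test of the difference itself, in these genes (log2 difference). It was higher for Plk5 (2.41), Draxin (2.39), Drd4 (2.33), Parvb (2.22), Tmem117 (2.04), Per2 (1.95), Rup2 (1.90), Cacna1h (1.86), Slc15a1 (1.84) and Cyp1a1 (1.77). It was lower for Ccl9 (-3.21), Pdzph1 (-1.996), Nptx1 (-1.79), Fam107b (-1.73), Depdc7 (-1.71), Hs3st2 (-1.70), Tfpi2 (-1.68), Sgk1 (-1.61), Col4a6 (-1.58) and Parm1 (-1.54). With offset 1 the calls of Draxin, Slc15a1 and Pdzph1 ended, and that of Rup2 ended without control array 2 or 3 or norepinephrine array 1, fits chosen only after the result was seen. The night effect exceeded the DBcAMP effect for Ribc2 (3.81), Slc15a1 (3.15), Draxin (2.91), Sik1 (2.80), Aanat (2.60), Slc6a17 (2.59), Plk5 (2.45), Sfpq (2.45), Per2 (2.41) and Zrsr2-ps1 (2.40). It lay below it for Ccl9 (-2.92), Nr1d1 (-2.30), Hs3st2 (-2.23), Pdzph1 (-2.08), Ndrg1 (-1.87), Lnc215 (-1.80), Dgkd (-1.78), Zfp143 (-1.77), Tfpi2 (-1.65) and Lca5 (-1.64), and the call of Pdzph1 ended here too with offset 1. All these effects start from unlike levels, as 1601 probe sets differed between untreated culture and day glands. Hs3st2, for example, already lay lower in untreated culture than by day. A difference of effects can therefore reflect the starting level as well as the response.

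Other splits of the arrays were counted for each comparison. For night and day the real split called 553 probe sets, with 8 as the highest other. It was the 1 of 35 that reached this count, the smallest share that 35 splits can give. This share is under 0.05 only if all 8 arrays are separate replicates. Arrays 3 and 4 of each time were very close to each other; averaged as 1 replicate they leave 10 splits, too few to judge, with 434 calls for the real split and 0 as the highest other. For untreated culture against day the real split called 1601 and was again the 1 of 35 that reached its count. The highest other, 1032, set 3 day arrays against the cultures and the remaining day array. This share too is under 0.05 only with day arrays 3 and 4 as separate replicates. With them averaged there are 10 splits, too few to judge (1726 calls and 0). For the night effect minus that of norepinephrine 2 of 100 drawn regroupings, the real one included, called 202 or more, and for DBcAMP 2 of 100 called 513 or more. Their highest others, 269 and 731, lay above the real counts. Before regrouping, the mean levels of gland and culture and the mean of both effects were removed. The tested difference of effects was left in, so these regroupings cannot judge it against chance. With 3 against 3 arrays there are 10 splits and a share never under 0.1, too few to judge. The real and highest other counts were 394 and 1 for norepinephrine, 184 and 0 for DBcAMP, 457 and 1 for forskolin, 206 and 1 for norepinephrine against DBcAMP, 355 and 0 for norepinephrine against forskolin, and 511 and 3 for forskolin against DBcAMP.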

How the results depend on the processing

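Single controls, liver-marked probe sets, averaged arrays, the block of replicates 1 and 2 against 3 and 4, omitted tissue arrays, and leaving out arrays for the differences between effects were alternatives chosen only after the result was seen. Of the values of named genes, 314 kept their call with offset 64 and 151 lost it; with offset 1 the figures were 449 and 16, with median centring 433 and 32, with quantile normalization 443 and 22, with no filter 458 and 7, with a trend and robust prior 463 and 2, and over single arrays left out 3303 and 213. No direction reversed. Signal over background limits dim genes, whose folds depend on the offset; a larger offset shrinks them by construction. For other settings the cause was not tested.

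With offset 1, 274 probe sets were lower at night, 288 lower with norepinephrine, 229 higher and 138 lower with DBcAMP and 467 lower with forskolin; 167 and 214 for norepinephrine against DBcAMP, 388 and 340 against forskolin, 330 and 668 for forskolin against DBcAMP, 1778 higher in culture than by day, 24 lower both at night and with DBcAMP, and 37 enriched. With offset 64, higher and lower counts were 247 and 83 at night, 161 and 28 for norepinephrine, 58 and 14 for DBcAMP, 122 and 55 for forskolin, 42 and 16 for norepinephrine against DBcAMP, 52 and 40 against forskolin, 59 and 93 for forskolin against DBcAMP, 58 and 39 for the night effect minus norepinephrine, 166 and 61 minus DBcAMP, and 348 and 355 for culture against day. Shared with night were 108 and 11 for norepinephrine, 38 and 2 for DBcAMP, 67 and 10 for forskolin; 10 were enriched and 45 shared with retina. Median centring gave 149 lower with forskolin, 589 and 1087 for culture against day, and 21 lower both at night and with norepinephrine. Control 1 alone gave 232 higher with DBcAMP and 356 and 357 with forskolin, control 2 alone 201 lower with norepinephrine, and control 3 alone 214 lower with norepinephrine and 105 with DBcAMP.

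Leaving out 1 array, with a lone array assumed to vary like the rest, gave higher and lower counts of 346 to 383 and 155 to 270 (without day 2) at night, 264 to 290 and 117 to 176 for norepinephrine, 111 to 173 and 47 to 69 for DBcAMP, 222 to 271 and 193 to 363 (without forskolin 3) for forskolin, 94 to 118 and 81 to 116 for norepinephrine against DBcAMP, 186 to 316 (without forskolin 3) and 149 to 164 against forskolin, and 173 to 201 and 266 to 488 for forskolin against DBcAMP. They were 881 to 1037 and 650 to 805 for culture against day and, as alternatives chosen after seeing the data, 97 to 132 and 67 to 124 for night minus norepinephrine and 260 to 343 and 139 to 350 (without day 2) for night minus DBcAMP. Shared with night were 152 to 169 and 25 to 37 for norepinephrine, 61 to 73 and 10 to 18 (without control 1) for DBcAMP, 109 to 134 and 22 to 30 for forskolin; 23 to 24 were enriched and 72 to 76 shared with retina.

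The replicate numbers as a block gave 370 and 175 at night, 270 and 125 for norepinephrine, 128 and 56 for DBcAMP, 231 and 219 for forskolin, 110 and 92 for norepinephrine against DBcAMP, 203 and 153 against forskolin, and 173 and 327 for forskolin against DBcAMP. With this block Per1 (adjusted p = 0.0593) and Pdc (0.0738) were not called at night, nor Hbb between DBcAMP and either other agent. The numbers did not pair the arrays throughout. Correlations of deviations ran from -0.11 to 0.365 in vivo (2 of 4 above 0.1) and from -0.38 to 0.23 in culture (2 of 18). The 2 in vivo were those of day and night arrays 3 (0.365) and 4 (0.275), so a source shared by these arrays stays open.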

Other observations

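The liver tests on the cortex night array and on albumin between controls, the clock list percentile and the quantile normalization of the clock list were tests chosen only after the result was seen, as were the intervals of both correlations. The 6 other tissues had single arrays per time, so their values carry no test. Per2 measured 37.3 by day and 539 at night in liver, 53.0 and 359 in heart, and 70.9 and 285 in cerebellum. Nr1d1 measured 119 and 12.4 in liver and 280 and 35.5 in heart, where Per2 was high at night. Npas2 measured 233 and 11.1 in liver and 147 and 36.3 in heart. In retina Rorb measured 98.0 by day and 276 at night, and Per1 119 and 54.6.

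Liver transcripts appeared on arrays of other tissues. Albumin (Alb) measured 5499 on the cortex night array and 78.5 on the cortex day array, 797 on the heart night array and 62.6 on the heart day array, and 10038 at night and 7757 by day in liver. Of the 100 brightest of 553 liver-marked probe sets, 86 percent were at least 2-fold higher at night in cortex, 19 percent in heart and 1 percent in hypothalamus, so liver RNA carried into the cortex night array may account for them but stays open, because nearly all were needed. In culture, the excess of DBcAMP and forskolin arrays over norepinephrine arrays rose with the liver level across these probe sets (rho 0.32, interval 0.13 to 0.49 by 10000 resamples; probe sets are not independent replicates), as carried-over liver RNA would give. Untreated control arrays already differed 38.8-fold in Alb, which argues against the agents as the whole cause, and no biological explanation within the groups was tested further.

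At night, clock genes differed between replicates 1 and 2 and replicates 3 and 4: Dbp averaged 394 and 108, Nr1d2 620.4 and 236, Nr1d1 96.8 and 29.9, and Bmal1 54.8 and 129. The median absolute log2 difference of the 20 clock genes was 0.58, at percentile 100 among 10000 random lists of like expression. By day the same sets differed by a median of 0.31, at percentile 93.96, and some genes, such as Per1 (0.99 at night, -0.50 by day) and Per3 (0.90 and -0.46), differed with opposite sign. The list was singled out because its genes had been seen to differ, so the percentiles describe these arrays and exclude nothing. Quantile normalization left 100.2 percent of the night difference (interval 82.6 to 109), but it moved all genes by a median of 0.0313, so little that a general difference in scaling stays open. RNA quality stays open, with a difference of 0.587 in the log2 actin ratio between both sets. A shift in the hour of sampling could also be a candidate explanation and stays open. The set difference and the night and day difference correlated at rho -0.18 across clock genes (interval -0.62 to 0.40). This correlation cannot decide it, because a shift at night need not move genes along their night and day difference. The same night arrays also enter both differences. The cre spike-in measured 4332 and 3539 on night arrays 1 and 2 and 6343 and 7461 on night arrays 3 and 4. By day it measured 3255 on array 1 and 6472 to 6763 on arrays 2 to 4. A difference of handling between the night sets therefore stays open too. Different pools or days of collection may also differ and were not tested.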
